A study of Homo sapiens with 21 samples.

How the data were processed

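Messenger RNA was measured by sequencing in 21 libraries of human chondrocyte sheets, 8 named NAC and 13 named PDC. Per the labels' protocols, the cells were grown in DMEM-F12 with serum, RNA was taken from harvested sheets with a column kit, poly-A RNA was selected, and 1 μg of RNA entered a NEBNext Ultra preparation. The labels describe the NAC cells as adult chondrocytes. The study design names adult and juvenile cartilage, so PDC is taken as the juvenile group by elimination. The meaning of the abbreviations, of the letter D that precedes each number in the sample titles and is dropped here, and of the letters f and t on 3 PDC names is not given in the sources used here. Nothing in the labels says that the libraries came from separate donors, so p-values measure the spread between these samples, part of which can be technical.

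The deposited table holds 60656 genes, of which 24120 were at 0 in every library. Trimmomatic 0.38, STAR 2.7.5b, featureCounts 1.6.4, MultiQC, DESeq2 1.22.1 and build hg38 are named in the submitters' processing notes. The annotation release and the use of strand in counting are not given in the sources used here, so reads of a gene and of an overlapping or antisense partner cannot be separated. Of the 80 named genes, 11 overlap another tested gene on the same strand and 37 on the opposite strand, and their levels are uncertain to that extent. The values deposited by the authors are a normalised signal: gene read counts divided by 1 size factor per library. The step between values gave whole reads for 100% of values within 0.01 read, with size factors of 0.7667 to 1.3095 and totals of 19.19 M to 27.63 M reads per library. The deposited table also gives the authors' mean signal, a log2 fold change with its standard error and Wald score, and a p-value with its adjusted form, per the file headers. Those columns were used for the authors' counts of calls, for their overlap with the calls made here and for a comparison of means. The authors' mean differed from the mean of the 21 columns for 182 genes and was lower for 180 of them.

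The design fixed before the data were examined assumed raw counts and edgeR. The table holds normalised values, so the fallback fixed at the same time became the main test: limma 3.58.1 with a mean-variance trend on log2(value + 1), with the group as the only term. Genes with a mean of at least 1 normalised count in a group were kept. Y-linked genes, XIST and its antisense gene, 568 in all, were left out, and 23715 genes were tested. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called a change. A log2 difference is PDC minus NAC on the log2(value + 1) scale, which understates the change of low genes. Adjusted p-values given for genes are from limma. Where a group held 1 to 3 reads in all, the ratio of reads is given with its 95% counting interval, and where it held 0, a bound against a floor of 3 reads over the group. Intervals and floors cover counting error only.

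The lists of genes (22 of biology and 15 of markers of other cell types or of RNA quality), the naming rule and the alternatives were also set before the data were examined. All 937 members were matched to the table. Named genes were the 8 largest increases and 8 largest decreases among called genes with an average log2 CPM of at least 2 and the same direction with each library left out, 10 genes fixed in advance, the 2 members with the smallest p in each biology list, and the most abundant member of each marker list, 80 genes in all, of which 2 are not reported here. Lists were tested two-sided with limma's camera at a preset correlation of 0.01, adjusted over 37 lists. Camera with an estimated correlation, camera at 0.05 and fry were alternatives. Library measures were compared by two-sided exact permutation over all 203490 splits into 8 and 13. Principal components used the 1000 most variable tested genes. Correlations used exact permutation for NAC and 100000 permutations for PDC.

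Alternatives were a pseudocount of 0.1, no filter beyond 1 read, at least 1 CPM in at least 8 libraries, upper-quartile scaling, edgeR 4.0.16 with robust dispersion, DESeq2 1.42.0, limma-voom with and without library weights, summing PDC 19f with PDC 19t, leaving out the 3 libraries with a letter, a replicate block and leaving out each library. Alternatives chosen after seeing the data were edgeR's quasi-likelihood test on the recovered reads, which called 2801 genes, TMM scaling, and leaving out NAC 5, PDC 14 and PDC 16. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

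The tests were run on simulated data for the PDC against NAC comparison, drawn from the real means and library sizes, with 67 genes changed 1.5-fold, 69 changed 2-fold and 64 changed 4-fold. In 22881 genes run, limma-trend recovered 41.8% of genes changed 1.5-fold, 66.7% of those changed 2-fold and 93.8% of those changed 4-fold, and 7 of its 141 calls were false. On the same draw 16.1% of DESeq2's calls were false. Camera called the 1 raised list and 0 of 20 unchanged lists. The genes were simulated independently of each other, so this draw cannot show how camera behaves where the genes of a list are correlated. The changed genes were taken from the better expressed ones only, so recovery of low genes was not measured.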

Results

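Gene expression was compared between chondrocyte sheets of the NAC group (n = 8, adult chondrocytes) and of the PDC group (n = 13, the juvenile group by elimination). Depth ran from 19.61 M to 27.63 M reads in NAC and from 19.19 M to 26.04 M in PDC, with means of 23.11 M and 22.13 M (exact permutation p = 0.408). Levels below are mean normalised read counts ± SD over the 8 NAC and 13 PDC libraries, and log2 differences are PDC minus NAC ± SE. Coordinates are those of build hg38. COL1A1, the main chain of fibrous collagen, took the largest mean share of reads in both groups, 3.45% ± 2.43 in NAC and 3.54% ± 3.18 in PDC. FN1, a cell adhesion glycoprotein, took 2.36% ± 0.73 and 1.93% ± 0.532, and CHI3L1, a secreted chitinase-like protein, 2.50% ± 1.56 and 0.84% ± 0.764 (limma adjusted p = 0.101). No pair of libraries within a group was alike within sampling noise, since the lowest of 106 chi-square values per degree of freedom was 24.35, and PDC 19f and PDC 19t, which share a number, gave 131.2.

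The question asked by the design is how sheets from adult and from juvenile cartilage differ in their transcripts. The labels do not give the limb origin of the cells, and genes of limb position differed between the groups. Effects of age and of origin therefore cannot be told apart in any difference below. Between the groups 2945 of 23715 genes changed (limma adjusted p under 0.05), 1415 higher and 1530 lower in PDC. Among them were genes of limb position in both directions and 25 of 30 interferon response genes, which fell. A change of at least 2-fold was found for 1508 genes, 794 higher and 714 lower. In 259 genes every PDC library lay on 1 side of every NAC library, where chance gives 0.000983% of genes. The authors' deposited table lists 3597 genes at an adjusted p under 0.05, 1826 higher and 1771 lower in PDC, and 2789 of the genes called here are among them, each in the same direction.

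The first principal component held 37.7% of the variance and separated the groups. Its scores were −45.4 ± 5.53 in NAC and 27.9 ± 12.9 in PDC, a difference of 73.3 (exact permutation p = 4.91e-06, the smallest the splits can give). The second component (21.3%) ran within both groups, with a difference of −10.7 (exact permutation p = 0.419). PDC 16, PDC 14 and NAC 5 had its lowest scores, −56.5, −54.9 and −50.8. Contractile genes chosen after their values were seen ran along this component: TAGLN, an actin-binding protein of smooth muscle, ranged from 3680.7 to 76974.8 with its maximum in NAC 5, and NOTCH3, a pericyte receptor, from 698.8 to 50791 with its maximum in PDC 16. The distance of libraries from their group mean was 0.737 ± 0.088 log2 units in NAC and 0.757 ± 0.081 in PDC, a difference that the spread does not separate from 0 (exact permutation p = 0.619).

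**Figure D1:**
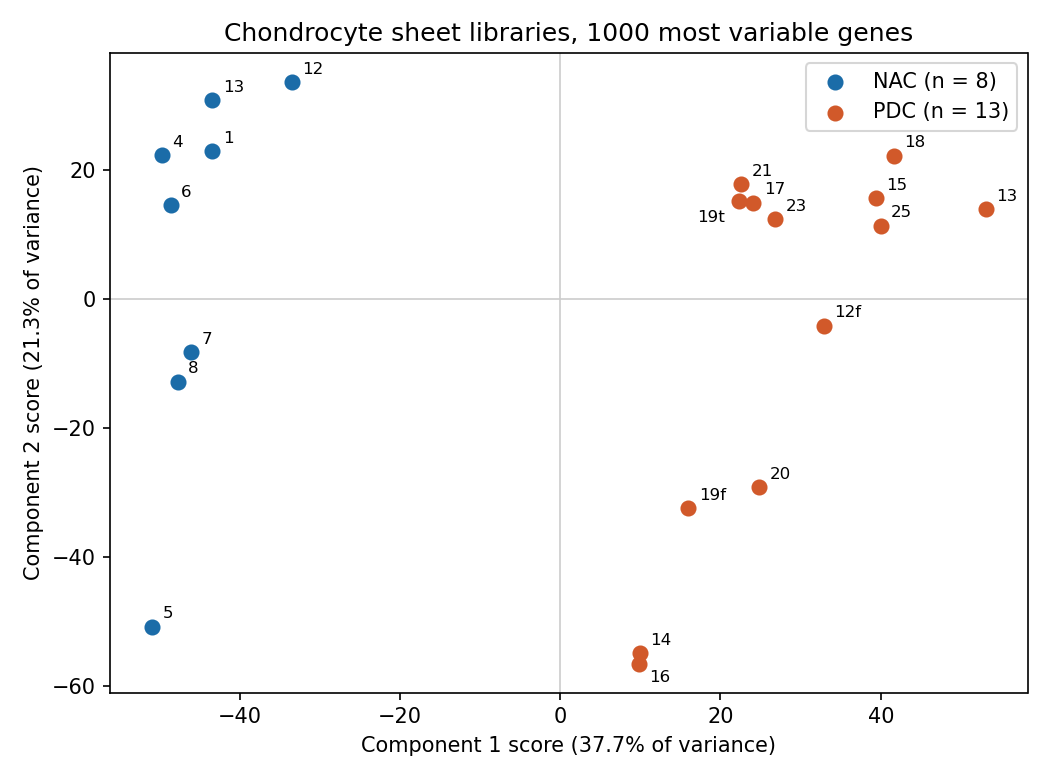
Scores of the 21 libraries on the first (37.7% of the variance) and second (21.3%) principal components, 1 point per library labelled by its replicate name, NAC in blue and PDC in orange. All NAC libraries lie at or below −33.5 on the first component and all PDC libraries at or above 9.8, and NAC 5, PDC 14 and PDC 16 lie below −50 on the second.

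Genes that mark position along the limb changed in both directions. Genes of the distal HOXA and HOXD clusters and TBX5, a forelimb transcription factor, were higher in PDC, while the HOXC genes, MEIS2, a proximal limb factor, and SHOX2, a regulator of limb bone growth, were lower. Of 41 measured members of the limb position list, 15 rose and 14 fell in PDC (16 and 14 adjusted over the list alone), and 12 did not pass. HOXD13 (ENSG00000128714.6, chromosome 2, 176092720 to 176095944) had 1 read in all NAC libraries and 6513 in PDC, a PDC to NAC ratio of 4020 (95% counting interval 721 to 159000; limma adjusted p = 2.46e-10). TBX5 (ENSG00000089225.20, chromosome 12, 114353910 to 114408442) had 3 reads in NAC and 4964 in PDC, a ratio of 1020 (349 to 4950; limma adjusted p = 6.63e-09). Its NAC mean of 0.479 was 0.174 without NAC 5. HOXD12, a list member chosen after its values were seen, had no read in NAC and was at least 186-fold higher in PDC against a floor of 3 reads over the group. HOXA13 (ENSG00000106031.9, chromosome 7, 27193502 to 27200091) rose from 27.4 ± 15.5 to 577 ± 220 (log2 4.50 ± 0.33, limma adjusted p = 3.26e-09). HOXD10 and HOXD11 rose by log2 7.49 ± 0.72 and 7.38 ± 0.60 (limma adjusted p = 1.77e-07 and 1.22e-08).

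MEIS2 (ENSG00000134138.20, chromosome 15, 36889203 to 37101299) fell from 383 ± 93.7 to 15.1 ± 9.46 (log2 −4.72 ± 0.27, limma adjusted p = 1.01e-10), the smallest p of any gene tested. SHOX2 fell from 670 ± 160 to 27.6 ± 22.9 (log2 −5.24 ± 0.58, limma adjusted p = 1.19e-06). HOXC10 (ENSG00000180818.5, chromosome 12, 53985064 to 53990279) fell from 833 ± 216 to 43.6 ± 99.3 (log2 −7.20 ± 0.94, limma adjusted p = 1.17e-05), and HOXC8, HOXC6, HOXC9 and HOXC4 fell by log2 −7.05 ± 0.67, −6.56 ± 0.73, −6.29 ± 0.71 and −6.22 ± 0.75 (limma adjusted p = 1.44e-07, 1.34e-06, 1.45e-06 and 4.26e-06). Within PDC, HOXC10 reached 338.6 in PDC 19t and 161.3 in PDC 23, against 46.9 or less in the other libraries. Its PDC mean was 19 without PDC 19t. The list as a whole had no direction by camera (adjusted p = 0.851), whose sign was up while the list's median and mean lay below 0. It holds distal with proximal and forelimb with hindlimb genes, so opposite changes cancel and camera cannot show a shift in position. HOXD10 overlaps HOXD11 on the same strand, HOXC6 overlaps HOXC4, HOXC8 and HOXC9, and TBX5, HOXA13, HOXC10 and SHOX2 have antisense or opposite-strand partners, so the level of each single gene is uncertain.

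**Figure D2:**
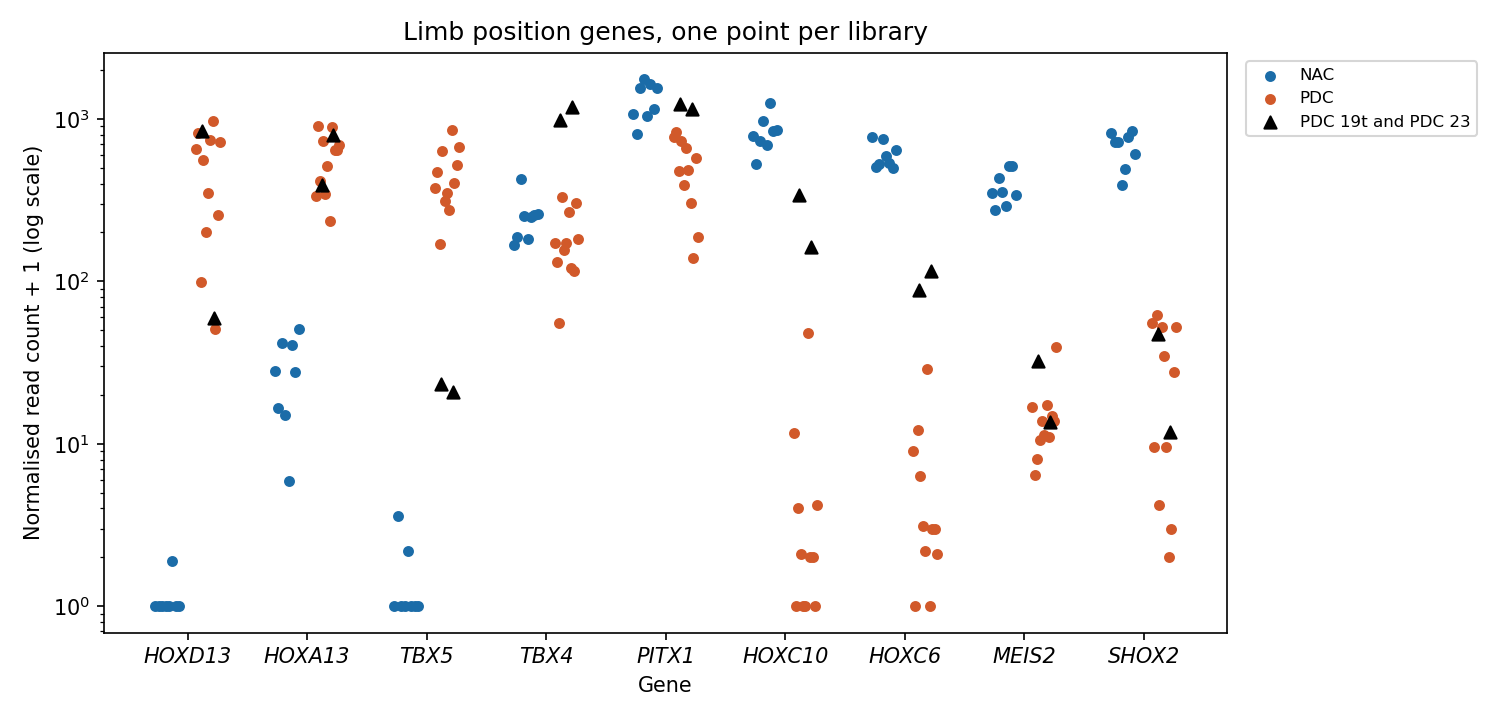
Normalised read count + 1 of 9 limb position genes on a log axis, 1 point per library, NAC in blue and PDC in orange, with black triangles for PDC 19t and PDC 23. HOXD13 has 1 NAC library above 0 (0.9 in NAC 4), and TBX4 lies at 984.9 and 1185.7 in PDC 19t and PDC 23 against at most 426.6 in NAC.

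The other named genes with the largest changes came from several families. SERPINB7, a protease inhibitor (ENSG00000166396.13, chromosome 18, 63752934 to 63805376), rose from 0.903 ± 1.37 to 1559 ± 1566 (log2 8.94 ± 0.69, limma adjusted p = 6.63e-09). Its NAC mean was 0.561 without NAC 13. SPINK13, another protease inhibitor, LHX9, a limb bud transcription factor, and STMN2, a neuronal microtubule regulator, rose by log2 7.13 ± 0.63, 6.56 ± 0.49 and 6.20 ± 0.90 (limma adjusted p = 5.44e-08, 4.14e-09 and 3.83e-05). KCNA4, a potassium channel, fell from 483 ± 279 to 9.45 ± 13.2 (log2 −6.21 ± 0.60, limma adjusted p = 1.71e-07). SPINK13 overlaps an opposite-strand gene. The call on STMN2 was lost with limma-voom (adjusted p = 0.0594).

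The transcript of COL2A1 was higher in PDC, while that of aggrecan was not separated. COL2A1, the main collagen of cartilage (ENSG00000139219.19, chromosome 12, 47972966 to 48004554), rose from 1.217 ± 1.186 to 240.4 ± 475.3 (log2 4.65 ± 0.90, limma adjusted p = 0.00102), and ranged from 3.6 to 1635.5 within PDC. The highest value was in PDC 13, without which the PDC mean was 124. ACAN, the core protein of aggrecan, was at 44220 ± 19900 in NAC and 48760 ± 22080 in PDC (log2 0.14 ± 0.28, limma adjusted p = 0.791). OGN, a small leucine-rich proteoglycan that overlaps an opposite-strand gene, fell from 1354 ± 984 to 57.7 ± 52.8 (log2 −4.46 ± 0.55, limma adjusted p = 6.11e-06). Members of the cartilage matrix list chosen after their values were seen, COL11A1, COL9A3 and COMP, rose by log2 1.57 ± 0.32, 3.00 ± 0.78 and 1.69 ± 0.49 (limma adjusted p = 0.00156, 0.0116 and 0.0251). COL9A3 went from 5.25 ± 4.88 to 139.2 ± 299.2, so its rise was uneven across PDC libraries. The PDC SD also exceeded the mean for COL2A1, COL9A2, COL11A2, SNORC and EPYC, which rose, but not for COL11A1, COMP and MATN4, which rose too. In this list 9 of 29 members rose and 2 fell (11 and 4 adjusted over the list alone), and camera's adjusted p was 0.0594 (adjusted p = 0.634 with an estimated correlation). It passed 0.05 without NAC 7 (0.0455), NAC 8 (0.0345), NAC 13 (0.042), PDC 16 (0.0355), PDC 19f (0.0404), PDC 20 (0.0425) or PDC 23 (0.0372), with PDC 19f and PDC 19t summed (0.0435), without the libraries with a letter (0.0449), with TMM (0.0483) and without the filter (0.0268). The list's falling members went from 2 to 1 without NAC 6 or NAC 7.

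Among regulators of chondrogenesis, SOX6, a partner of SOX9, rose from 90.6 ± 45.8 to 542 ± 193 (log2 2.69 ± 0.27, limma adjusted p = 2.35e-07), and SOX8 rose from 1.27 ± 1.51 to 11.5 ± 8.42 (log2 2.36 ± 0.45, limma adjusted p = 9.45e-04). The NAC mean of SOX8 was 0.835 without NAC 7. SOX9, the chondrocyte master regulator, was at 1529 ± 893 in NAC and 2494 ± 1918 in PDC (log2 0.65 ± 0.38, limma adjusted p = 0.282). Of 20 members 3 rose and none fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.475), although 3 fell without NAC 5 and 1 without NAC 7, NAC 13, PDC 13, PDC 14, PDC 15, PDC 16, PDC 18, PDC 19t or PDC 23. With edgeR's quasi-likelihood test 4 rose and 3 fell, with DESeq2 5 and 3, and 3 fell without NAC 5, PDC 14 and PDC 16 together. SOX6 and SOX9 overlap opposite-strand genes.

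Of 20 genes of hypertrophic cartilage and mineralization, 7 were higher in PDC. MMP13, the collagenase of hypertrophic cartilage (ENSG00000137745.12, chromosome 11, 102942994 to 102955732), rose from 237 ± 110 to 8402 ± 5679 (log2 5.04 ± 0.48, limma adjusted p = 1.37e-07). COL10A1, the collagen of hypertrophic chondrocytes, rose from 7.91 ± 7.78 to 40.9 ± 33.4 (log2 2.43 ± 0.56, limma adjusted p = 0.00504), and ENPP1, which makes pyrophosphate and so restrains mineral, rose by log2 1.98 ± 0.35 (limma adjusted p = 4.49e-04). None of the 20 fell, and the counts were the same adjusted over the list alone. Camera called the list up (adjusted p = 0.0213; adjusted p = 0.101 with an estimated correlation), and the call was lost without NAC 1 (0.0513). COL10A1 and ENPP1 overlap opposite-strand genes. ALPL, the alkaline phosphatase that feeds mineral, was at 541 ± 388 in NAC and 449 ± 550 in PDC (log2 −1.04 ± 0.78, limma adjusted p = 0.423).

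**Figure D3:**
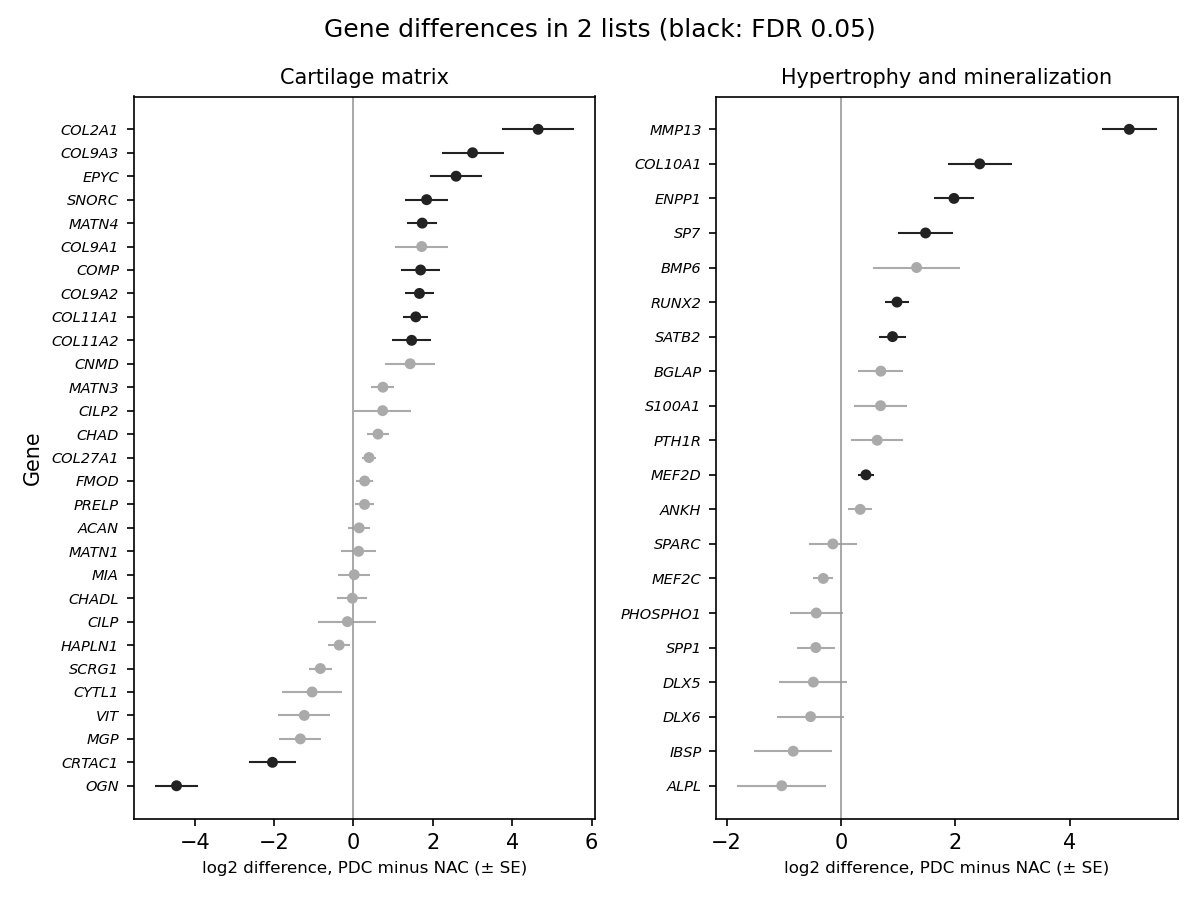
Log2 difference (PDC minus NAC) ± SE of each measured member of the cartilage matrix and the hypertrophy and mineralization lists, black where the limma adjusted p is under 0.05 and grey elsewhere. Black points number 9 above 0 and 2 below it among 29 cartilage matrix genes, and 7 of 20 above 0 in the hypertrophy panel; COL9A1 had no reads in NAC, so its plotted value depends on the added 1.

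Fibrous matrix genes were lower in PDC in a few members. TNXB, a tenascin of loose connective tissue, fell from 725 ± 376 to 109 ± 49.0 (log2 −2.68 ± 0.27, limma adjusted p = 3.03e-07), and COL14A1, a fibril-associated collagen, fell from 23800 ± 10620 to 7001 ± 3090 (log2 −1.77 ± 0.25, limma adjusted p = 3.66e-05). COL1A1 was at 826700 ± 634100 in NAC and 827200 ± 811100 in PDC (log2 −0.24 ± 0.58, limma adjusted p = 0.832). In the fibrous list 1 of 25 members rose and 3 fell (1 and 4 adjusted over the list alone), and camera called it down (adjusted p = 0.0136; adjusted p = 0.634 with an estimated correlation). The count of falling members went to 5 without PDC 14 or PDC 16, which sit low on the second component, or these and NAC 5 together. That of rising ones went to 0 without NAC 6 or NAC 12 and to 2 with DESeq2. TNXB overlaps genes on both strands and is uncertain.

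Other matrix lists moved both ways. ADAMTS12 rose by log2 2.44 ± 0.38 and ADAMTS15, an aggrecan and versican protease, changed by log2 −2.0 ± 0.32 (limma adjusted p = 9.82e-05 and 1.30e-04), and 3 of 34 matrix proteases and inhibitors rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.651), with 5 falling without NAC 5 alone or NAC 5, PDC 14 and PDC 16 together and 6 with DESeq2. HAS2, a hyaluronan synthase, rose from 1946 ± 705 to 7698 ± 2934, while SULF2, a heparan sulfatase, fell from 3826 ± 1221 to 1043 ± 345 (log2 1.99 ± 0.24 and −1.87 ± 0.21, limma adjusted p = 3.70e-06 and 1.63e-06). In the glycosaminoglycan synthesis list 3 of 39 rose and 9 fell (6 and 10 adjusted over the list alone; camera adjusted p = 0.118), with 5 rising without NAC 5 and 1 with edgeR. The list also holds genes that degrade or edit these chains. Of these SULF2, SULF1, HYAL1 and CEMIP were among those that fell, so the falling count is not one of synthesis alone. FBLN5 fell and LOXL3, a crosslinking oxidase, rose (log2 −1.25 ± 0.17 and 0.92 ± 0.17, limma adjusted p = 1.38e-05 and 6.15e-04). Elastic fibre genes split evenly, with 4 of 20 up and 4 down (4 and 5 adjusted over the list alone; camera adjusted p = 0.573). PRG4, the boundary lubricant lubricin (ENSG00000116690.13, chromosome 1, 186296278 to 186314567), fell from 505 ± 595 to 29.1 ± 24.9 (log2 −3.24 ± 0.71, limma adjusted p = 0.00328), and ENG, a TGF-beta co-receptor, fell by log2 −1.04 ± 0.18 (limma adjusted p = 2.54e-04). In the lubricin and superficial zone list 3 of 20 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.475). For the elastic fibre and protease lists the median lay below 0 and the mean above it, with camera's sign down. HAS2, SULF2, LOXL3, PRG4 and ENG overlap opposite-strand genes.

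Interferon response genes were lower in PDC as a group. DDX58, the RNA sensor RIG-I (ENSG00000107201.10, chromosome 9, 32455301 to 32526208), fell from 505 ± 119 to 224 ± 42.7 (log2 −1.16 ± 0.14, limma adjusted p = 2.32e-06), and every PDC library lay below every NAC library. IFI27 and OAS2, chosen after their values were seen, fell by log2 −4.22 ± 0.55 and −3.64 ± 0.56 (limma adjusted p = 1.09e-05 and 8.44e-05). None of 30 measured members rose and 25 fell (28 adjusted over the list alone), with a median log2 difference of −1.48. Camera called the list down (adjusted p = 3.47e-26; adjusted p = 0.0591 with an estimated correlation), and between 24 and 27 members fell with each library left out in turn. Blood cell markers went both ways: HBB had 194 reads in NAC and 2 in PDC, and CD79B, a B cell marker chosen after its values were seen, fell from 51.6 ± 20.6 to 3.97 ± 4.14 (limma adjusted p = 2.24e-06). IL7R, the most abundant member of the lymphoid list, rose from 411 ± 229 to 1969 ± 954 (limma adjusted p = 7.77e-06). PTPRC of the same list was low in both groups, at 2.18 ± 1.58 and 3.69 ± 2.84 (limma adjusted p = 0.439). The rise of IL7R alone therefore does not show more lymphoid cells.

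Among genes of MHC class I presentation, immunoproteasome subunits and 1 regulator were lower in PDC. PSMB10 and PSMB8, catalytic subunits of the immunoproteasome, fell by log2 −0.73 ± 0.13 and −0.59 ± 0.11 (limma adjusted p = 3.16e-04 and 4.75e-04), and 4 of 17 members fell and none rose (5 and 0 adjusted over the list alone). The others, chosen after their values were seen, were NLRC5, an activator of class I genes, and PSMB9, which changed by log2 −0.93 ± 0.19 and −0.82 ± 0.21 (limma adjusted p = 0.00201 and 0.0106). Camera called the list down (adjusted p = 0.00255; adjusted p = 0.0997 with an estimated correlation). Reads of the HLA genes can be split between paralogs. CD74, the class II invariant chain, was at 712 ± 378 in NAC and 342 ± 205 in PDC (log2 −1.16 ± 0.39, limma adjusted p = 0.0524), and HLA-DPA1 differed by log2 −0.86 ± 0.40 (limma adjusted p = 0.165). CD74 passed 0.05 without NAC 5 (0.026), NAC 8 (0.0422), PDC 13 (0.0305), PDC 15 (0.0364), PDC 17 (0.0477) or PDC 18 (0.0401), and under 9 other settings, among them edgeR (0.0464) and DESeq2 (0.0297). None of 11 class II members passed, also adjusted over the list alone (camera adjusted p = 0.147), although 1 did without NAC 5, NAC 8, PDC 13, PDC 15, PDC 17 or PDC 18, with edgeR, DESeq2, TMM or upper-quartile scaling, and without NAC 5, PDC 14 and PDC 16 together, and the list passed without the filter (0.0485). PSMB8, PSMB10, CD74 and HLA-DPA1 overlap other genes.

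Among inflammatory genes PTGS2, the inducible prostaglandin synthase, rose from 1060 ± 449 to 7692 ± 2818 (log2 2.89 ± 0.27, limma adjusted p = 1.17e-07), and CSF1, a macrophage growth factor, fell from 7478 ± 1378 to 2042 ± 630 (log2 −1.91 ± 0.17, limma adjusted p = 4.28e-08). The list had 3 of 39 members up and 5 down (3 and 10 adjusted over the list alone; camera adjusted p = 0.118), and it passed without the filter (0.0352). The falling count was 9 without NAC 5 and 8 with DESeq2 or without NAC 5, PDC 14 and PDC 16 together.

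Signalling genes rose and fell within each pathway. DKK1, a secreted WNT inhibitor (ENSG00000107984.10, chromosome 10, 52314280 to 52318042), rose from 71.2 ± 38.6 to 2826 ± 2268 (log2 5.08 ± 0.40, limma adjusted p = 6.63e-09), and WNT16 rose from 1.12 ± 1.82 to 41.1 ± 40.8 (log2 4.04 ± 0.53, limma adjusted p = 1.09e-05). The NAC mean of WNT16 was 0.52 without NAC 12. Of 35 WNT members 7 rose and 4 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.118), and fry, which asks whether the members move one way, called the list up (adjusted p = 0.0175). With edgeR or DESeq2 11 rose. The 4 that fell, named after their values were seen, were LEF1, RSPO2, ROR2 and WNT2B (log2 −2.64, −4.32, −1.66 and −1.45, limma adjusted p = 3.45e-05, 4.08e-05, 0.0027 and 0.00579). The list holds WNT ligands and their inhibitors together, so its sign is not that of the pathway. NOG, a secreted BMP inhibitor, rose from 3.03 ± 3.87 to 157 ± 158 (log2 5.18 ± 0.58, limma adjusted p = 1.34e-06), with a NAC mean of 1.78 without NAC 1, and ACVR1, a BMP receptor, fell by log2 −0.57 ± 0.08 (limma adjusted p = 3.08e-05). In the TGF-beta and BMP list 8 of 37 rose and 3 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.513), with 5 falling without PDC 16. KIF7 and GLI3 of the hedgehog list fell by log2 −0.58 ± 0.09 and −0.67 ± 0.12 (limma adjusted p = 8.90e-05 and 5.80e-04). Of 15 hedgehog members 1 rose and 3 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.206). The rising member was PTCH1 (log2 0.84 ± 0.18, limma adjusted p = 0.00316), named after its values were seen. There were 2 rising without NAC 12 or with DESeq2, and 5 falling without NAC 5, PDC 14 and PDC 16 together. Whether the pathway was more or less active was not tested. For the hedgehog list the median lay below 0 and the mean above it, with camera's sign down. DKK1 and KIF7 overlap opposite-strand genes.

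Growth factor genes moved in both directions. VEGFA, the vascular growth factor, rose from 6480 ± 2515 to 15790 ± 4231 (log2 1.31 ± 0.21, limma adjusted p = 1.30e-04), and NRG1 rose by log2 2.36 ± 0.42 (limma adjusted p = 4.48e-04). Of 36 members 6 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.475). The falling count was 1 without NAC 8 and 2 without NAC 1, NAC 4, NAC 6, NAC 7, NAC 13, PDC 13, PDC 18, PDC 21 or PDC 25.

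Of 25 fetal and imprinted growth genes, 8 were higher and 2 lower in PDC. IGF2BP3, a fetal RNA-binding protein, rose from 20.9 ± 9.71 to 216 ± 82.0 (log2 3.35 ± 0.33, limma adjusted p = 2.22e-07), and PEG10, an imprinted gene, rose by log2 1.46 ± 0.32 (limma adjusted p = 0.00355). IGF2, a fetal growth factor, fell from 27.0 ± 21.1 to 5.36 ± 8.80 (log2 −2.81 ± 0.71, limma adjusted p = 0.00928), a call lost with DESeq2 (adjusted p = 0.101). GRB10, an imprinted growth inhibitor chosen after its values were seen, fell by log2 −0.42 ± 0.12 (limma adjusted p = 0.0155). Adjusted over the list alone, 11 rose and 4 fell, and camera called the list up (adjusted p = 0.0136; adjusted p = 0.109 with an estimated correlation). IGF2BP3, PEG10 and IGF2 overlap opposite-strand genes.

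Senescence genes did not move together. HGF, a secreted growth factor in the list (ENSG00000019991.18, chromosome 7, 81699009 to 81770438), rose from 18.4 ± 12.6 to 978 ± 683 (log2 5.71 ± 0.57, limma adjusted p = 2.86e-07), and TNFRSF11B, the osteoclast inhibitor osteoprotegerin, fell from 2570 ± 1656 to 279 ± 144 (log2 −3.30 ± 0.41, limma adjusted p = 5.12e-06). Of 26 members 4 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.475, its sign down, with a median below 0 and a mean above it).

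No single cell cycle gene passed. MKI67, a proliferation marker, was at 1474 ± 451 in NAC and 1872 ± 805 in PDC (log2 0.30 ± 0.23, limma adjusted p = 0.436), and CDK1 and CCNA2 differed by log2 0.48 ± 0.20 and 0.45 ± 0.21 (limma adjusted p = 0.126 and 0.176). None of 36 members passed, also adjusted over the list alone, and CDK1 passed without PDC 15 (0.0482). Camera called the list up (adjusted p = 0.0136; adjusted p = 0.682 with an estimated correlation), a call lost without NAC 1 (0.131), NAC 13 (0.0539), PDC 14 (0.113), the 3 libraries with a letter (0.0672), or NAC 5, PDC 14 and PDC 16 together (0.173).

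Hypoxia and glycolysis genes were higher in PDC in a few members. ENO2, a glycolytic enolase, and CA9, a hypoxia-induced carbonic anhydrase, rose by log2 0.99 ± 0.22 and 1.95 ± 0.48 (limma adjusted p = 0.0042 and 0.00844), and 5 of 32 members rose and 1 fell (9 and 1 adjusted over the list alone). The rising count was 2 without NAC 1, NAC 6, NAC 12, PDC 17, PDC 18 or PDC 20, 3 without PDC 13, PDC 16, PDC 19f or PDC 23, 8 without NAC 13 or PDC 15, and 9 without PDC 19t. It was 8 with PDC 19f and PDC 19t summed and 2 without NAC 5, PDC 14 and PDC 16 together. Camera called the list up (adjusted p = 0.0213; adjusted p = 0.634 with an estimated correlation), a call lost without NAC 1 (0.056), NAC 12 (0.135), PDC 14 (0.0534), PDC 17 (0.057) or NAC 5, PDC 14 and PDC 16 together (0.1). In cholesterol synthesis STARD4, a sterol carrier, rose by log2 1.17 ± 0.24 (limma adjusted p = 0.00185). Of 24 members 3 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.263), with 1 rising without NAC 5 or NAC 13 1 falling without NAC 1, NAC 6, NAC 7 or NAC 8, and 0 falling without the 3 libraries with a letter.

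**Figure D4:**
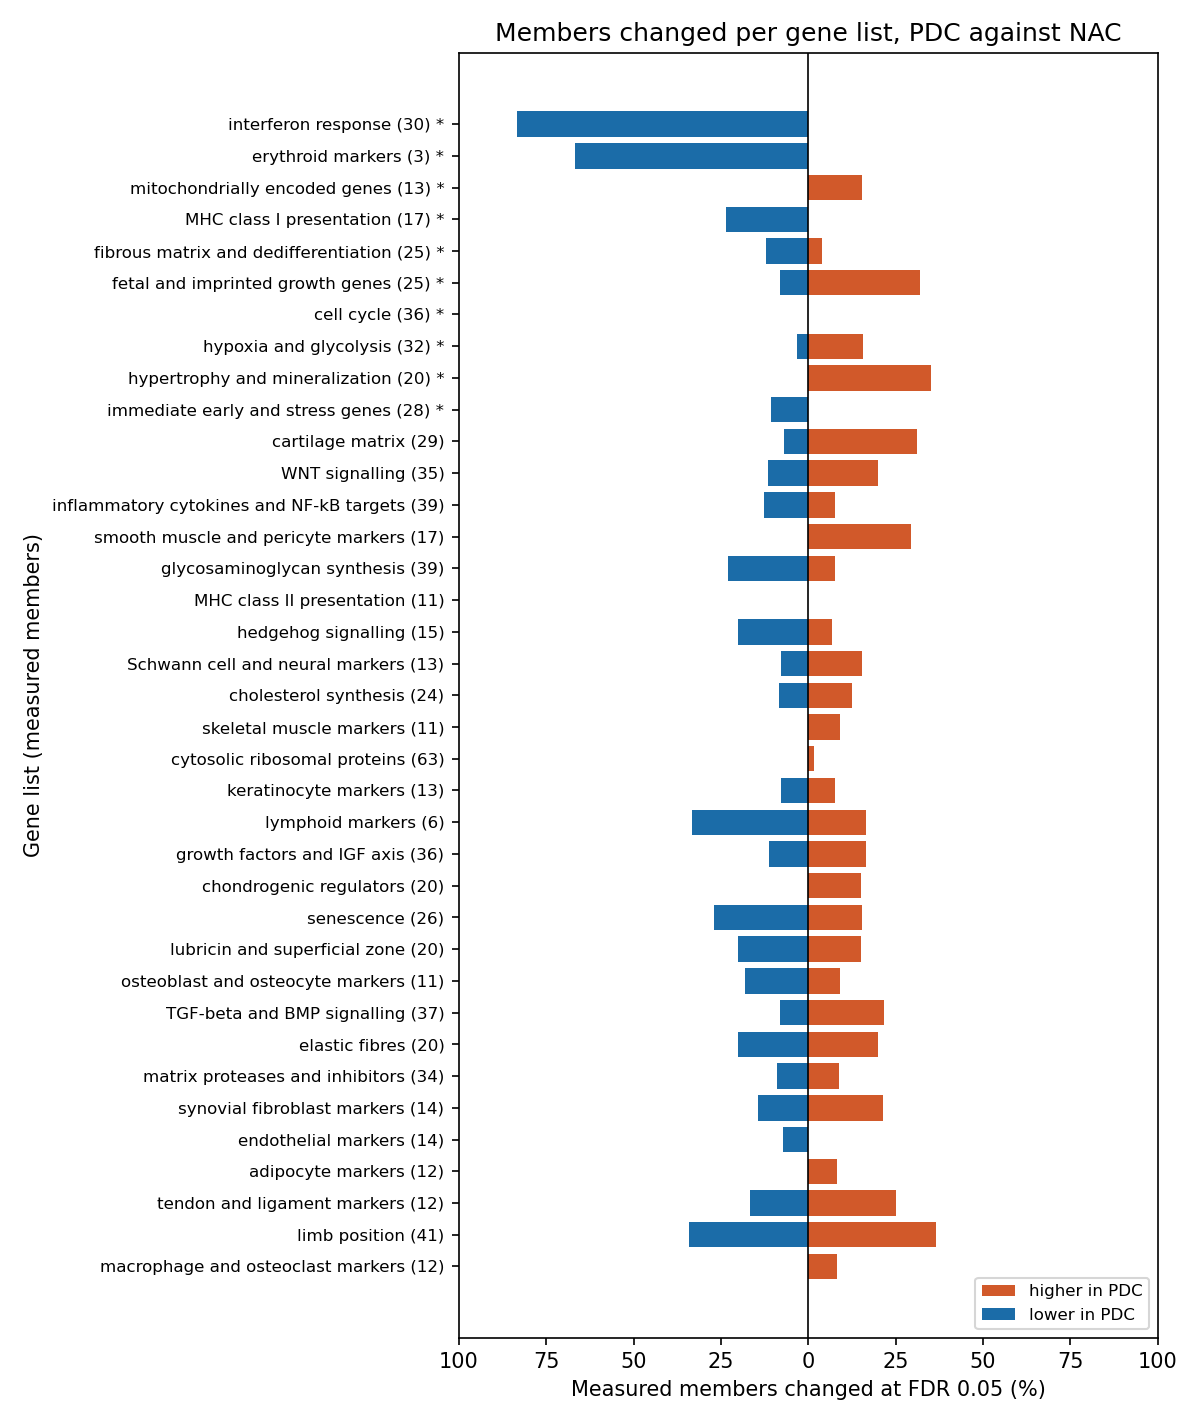
Percent of the measured members of each of the 37 lists that were higher (orange, right) or lower (blue, left) in PDC at a limma adjusted p under 0.05, with the number of measured members in brackets and a star where camera's adjusted p is under 0.05. The interferon response list has 25 of 30 members lower, and the cell cycle list has a star and no member changed.

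Of 5 library measures, the mitochondrial share differed between the groups. Transcripts encoded by the mitochondrial genome took 2.11% ± 0.271 of reads in NAC and 2.88% ± 0.577 in PDC (exact permutation p = 0.00204, adjusted p = 0.0102 over 5 measures). Genes detected (22920 ± 1104 and 23400 ± 556, p = 0.204), the ribosomal protein share (2.78% ± 0.144 and 3.05% ± 0.64, p = 0.258) and the share of the 10 most abundant genes (17.3% ± 2.77 and 15.4% ± 4.55, p = 0.286) did not pass by the same exact test, although the difference in genes detected passed without NAC 13 (exact p = 0.0493). Of 13 mitochondrial genes 2 rose and none fell (3 and 0 adjusted over the list alone), with 4 rising without NAC 5 and 1 without NAC 4 or NAC 6, and camera called the list up (adjusted p = 0.00251; adjusted p = 0.634 with an estimated correlation). MT-CO1, its most abundant member, was at 145500 ± 23620 in NAC and 183000 ± 36560 in PDC (log2 0.32 ± 0.17, limma adjusted p = 0.237). In the immediate early and stress list none of 28 rose and 3 fell (1 and 4 adjusted over the list alone), and HSPA5, an endoplasmic reticulum chaperone, differed by log2 −0.32 ± 0.16 (limma adjusted p = 0.196). Camera called that list down (adjusted p = 0.0375; adjusted p = 0.634 with an estimated correlation), a call lost without NAC 5 (0.156), NAC 7 (0.28), PDC 18 (0.0718), PDC 21 (0.0686), the 3 libraries with a letter (0.055), or NAC 5, PDC 14 and PDC 16 together (0.0735). Its falling count was 5 without PDC 14 or with DESeq2. Its rising count was 2 without NAC 7 and 1 without NAC 5, PDC 14 or PDC 19t, without NAC 5, PDC 14 and PDC 16 together, or with PDC 19f and PDC 19t summed. Of 63 ribosomal protein genes 1 rose (0 adjusted over the list alone; camera adjusted p = 0.475), and RPL13A differed by log2 −0.13 ± 0.14 (limma adjusted p = 0.607). That 1 became 0 without NAC 1, NAC 5, NAC 6, NAC 7, NAC 8, NAC 12, PDC 12f, PDC 13, PDC 18, PDC 19f, PDC 20, PDC 23 or PDC 25, and 2 without PDC 14 or PDC 21 or with edgeR or DESeq2.

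Among markers of blood cells, the globin transcripts were lower in PDC. HBB had 194 reads in NAC and 2 in PDC, a NAC to PDC ratio of 157 (95% counting interval 42.9 to 1310; limma adjusted p = 1.13e-04). The 2 PDC reads were in PDC 23 alone, without which PDC holds no HBB read and the ratio becomes a bound. Of 3 measured erythroid members 2 fell (3 adjusted over the list alone), and camera called the list down (adjusted p = 0.00199; adjusted p = 0.195 with an estimated correlation). Lymphoid markers went both ways, with 1 of 6 up and 2 down, also adjusted over the list alone (camera adjusted p = 0.475), and IL7R, an interleukin receptor, rose from 411 ± 229 to 1969 ± 954 (log2 2.31 ± 0.29, limma adjusted p = 7.77e-06). The falling count was 1 without NAC 1, NAC 4, NAC 5, NAC 6, NAC 7, NAC 8 or any PDC library other than PDC 12f, PDC 14 and PDC 17, with PDC 19f and PDC 19t summed, or without the 3 libraries with a letter. Of 12 macrophage and osteoclast markers 1 rose, also adjusted over the list alone (camera adjusted p = 0.96), and CTSK, a collagen-degrading protease, differed by log2 −0.69 ± 0.31 (limma adjusted p = 0.159). None fell with every library in the fit, 1 did without NAC 4, NAC 5, PDC 15 or PDC 21, and 2 did without NAC 12. The rising count was 0 with edgeR or without the 3 libraries with a letter.

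Some smooth muscle and pericyte markers and 1 skeletal muscle marker were higher in PDC. Of 17 smooth muscle and pericyte markers 5 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.118), and the list passed without NAC 5 (0.0194) or NAC 8 (0.0418). The 5, named after their values were seen, were CSPG4, KCNJ8, HEYL, SMTN and ABCC9. TAGLN was at 27360 ± 22660 in NAC and 18350 ± 18660 in PDC (log2 −0.90 ± 0.52, limma adjusted p = 0.284). The contractile genes ACTA2, MYH11 and CNN1 differed by log2 −1.25, −1.38 and −0.72 and did not pass (limma adjusted p = 0.442, 0.601 and 0.565). MYH3, an embryonic myosin, rose from 59.4 ± 52.9 to 379 ± 462 (log2 2.31 ± 0.54, limma adjusted p = 0.00591), the 1 of 11 skeletal muscle markers that changed, also adjusted over the list alone (camera adjusted p = 0.475). Of 14 endothelial markers 1 fell (0 adjusted over the list alone; camera adjusted p = 0.686), and ERG, also a regulator in articular chondrocytes, was at 3810 ± 1192 and 4685 ± 1311 (log2 0.29 ± 0.20, limma adjusted p = 0.371). The falling count was 0 without NAC 4, NAC 6, NAC 7, NAC 8, NAC 13, PDC 13, PDC 15, PDC 16, PDC 19f, PDC 19t, PDC 23 or PDC 25 and 2 without NAC 12 or PDC 20. It was also 0 with edgeR, with PDC 19f and PDC 19t summed or without NAC 5, PDC 14 and PDC 16 together, and 2 with DESeq2. Without PDC 23 or PDC 25, 1 member rose.

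For connective tissue and other markers, GAS6 rose by log2 0.87 ± 0.16 (limma adjusted p = 7.37e-04), and 3 of 14 synovial fibroblast markers rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.668, its sign up, with a median below 0 and a mean above it). BGN, a small proteoglycan, differed by log2 0.12 ± 0.24 (limma adjusted p = 0.794), and 3 of 12 tendon and ligament markers rose and 2 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.742). Of 11 osteoblast and osteocyte markers 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.483). PMP22, a myelin protein, fell by log2 −0.46 ± 0.13 (limma adjusted p = 0.0239), a call lost without NAC 1 (0.0611), NAC 6 (0.0648), NAC 13 (0.054) or the 3 libraries with a letter (0.0578), and 2 of 13 Schwann cell and neural markers rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.263). Of 12 adipocyte markers 1 rose (2 adjusted over the list alone; camera adjusted p = 0.714), and ADIPOR2 differed by log2 −0.10 ± 0.08 (limma adjusted p = 0.45). Of 13 keratinocyte markers 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.475), and PERP differed by log2 0.08 ± 0.18 (limma adjusted p = 0.834). Counts of 1 or 2 members in these marker lists moved by 1 or 2 with single libraries left out: for synovial genes, 1 fell without NAC 6 or NAC 7; for tendon genes, 1 fell without NAC 1, NAC 4 or NAC 6; for Schwann cell genes, 0 fell without NAC 1, NAC 6 or NAC 13; for adipocyte genes, 2 rose without NAC 12, PDC 14 or PDC 23. For osteoblast genes, 0 rose without NAC 1, NAC 4, NAC 5, NAC 6, NAC 7, NAC 8, NAC 12, PDC 12f, PDC 13, PDC 16, PDC 17, PDC 18 or PDC 19f. For keratinocyte genes, 0 rose without NAC 1, NAC 6, NAC 7, PDC 18, PDC 20 or PDC 25, while 3 fell without NAC 7 and 2 without NAC 4, NAC 12, PDC 14 or PDC 16. With edgeR, 0 osteoblast genes rose, 0 keratinocyte genes rose and 2 fell, and 2 adipocyte genes rose. With DESeq2, 0 osteoblast genes rose, 3 keratinocyte genes fell and 3 adipocyte genes rose. Without the 3 libraries with a letter, 0 osteoblast genes rose and 0 Schwann cell genes fell. Leaving out NAC 5, PDC 14 and PDC 16 together gave 0 rising osteoblast genes and 2 rising adipocyte genes, and upper-quartile scaling also gave 2 of the latter.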

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

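All tests of explanations in this part, and the count of other splits, were chosen after the results they bear on had been seen. Of 88 measures in the NAC libraries, 8 had a highest or lowest library whose gap to the next one, as a share of the whole range, exceeded Dixon's 95% critical value, where chance gives about 1 in 20, and 3 of the 8 were in NAC 5. HOXD13 was at 0.9 in NAC 4, from 1 read, and at 0 in the other NAC libraries. MKI67 was at 695.4 in NAC 1, with the next library at 1283. MMP13 was at 31.3 in NAC 5, with the next at 128.2. IGF2BP3 was at 4.3 in NAC 7, with the next at 14.7. NRG1 was at 57.3 in NAC 12, with the next at 29.3. ENG was at 4288.4 in NAC 5, with the next at 7623.5. The first component score of NAC 12 was −33.5, with the next at −43.4. The distance from the group mean was 0.94 log2 units in NAC 5, with the next at 0.736.

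Of 100 splits of the 21 libraries into 8 and 13, the real one included, 1 gave as many as 2945 changed genes, the real one, and the highest of the others gave 1478, in a split that kept 7 of the 8 NAC libraries together. For changes of at least 2-fold, 1 split gave as many as 1508, and the highest other gave 817. A random grouping of the libraries is thus an unlikely source of both counts, at the 1 in 100 that this number of splits can resolve. The splits treat the libraries as independent, which the labels do not show. For the 10 lists called by camera, 3 of 100 splits gave as many, the highest other gave 10 and the median of the others was 4. The share lies under 0.05, but 2 of the other splits also reached 10 with 0 changed genes, and 97 called at least 1 list at camera's preset correlation. With an estimated correlation 0 lists were called in the real split, so the number of lists is weak evidence.

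PDC 19t and PDC 23 held TBX4, a hindlimb transcription factor, at 984.9 and 1185.7, against at most 328.5 in the other PDC libraries and 426.6 in NAC, with TBX5 at 22.3 and 19.8 and HOXC10 at 338.6 and 161.3. A wrong label on 2 NAC libraries is argued against by genes outside the limb list, where the lower of the pair lay at 0.82 on an axis from NAC (0) to PDC (1), above the highest NAC library at 0.24 and within the other PDC libraries, the lowest at 0.7. RNA carried over from NAC sheets is argued against by 32 other genes low in PDC, whose upper quartile of excess was at most 3.61% of the NAC excess against HOXC medians of 27.5% and 16.2%, and by TBX4 at 984.9, above every NAC library; the limit that chose those genes was widened from 2% to 10% after the stricter one left 2 genes. A candidate explanation is another limb origin of the cells in these libraries, which the labels do not give and no test here addressed.

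Interferon response genes were lower in PDC, with 25 of 30 members called. A single NAC library is argued against by 24 members still called lower, at the fewest, with 1 NAC library left out. For a batch that follows the label number, the lower list mean of NAC 12 and NAC 13, 8.12, lay above the highest PDC mean of 7.75. That rests on NAC 12 and NAC 13 alone, and nothing shows that the number tracks processing, so it cannot exclude a batch. Among NAC libraries the list mean ran from 7.42 to 9.37, so the groups overlap. Blood cell markers, chosen after their values were seen, went both ways: PTPRC, LAPTM5 and TYROBP were at 2.18, 10.3 and 2.40 in NAC (TYROBP 1.58 without NAC 1) and 3.69, 20.0 and 3.42 in PDC, IL7R rose from 411 to 1969, and CD79B fell from 51.6 to 3.97 and HBB from 194 reads to 2. FCER1G was at 5.08 in NAC and 5.16 in PDC, and AIF1 (0.221 and 0.152) and CD52 (0.131 and 0.0825) were near 0. CD4 fell from 72.4 to 28.3 (limma adjusted p = 0.0476), and CD14, at 77.7 and 39.5, did not pass (limma adjusted p = 0.0831). RNA of other cell types in the NAC sheets and the age group that the design names stay open. So do a different limb origin of the groups and any culture or handling difference that follows them.

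A contractile gene axis ran within both groups, with ACTA2, a smooth muscle actin, from 243.5 to 44391.8 and MYH11, a smooth muscle myosin, from 0 to 2658.1. Read depth is argued against by a correlation of 0.05 between total reads and the axis, with a 95% upper bound of 0.48 on its size, chosen after thinning to equal depth left the axis at r = 0.9999 and so decided nothing. Vessel wall tissue with its endothelium stays open: the median correlations of 14 endothelial markers with the axis were −0.33 in NAC and −0.24 in PDC, but only 4 of them had a mean of 10 or more in both groups, and of these TEK rose along the axis (0.51 in NAC, 0.58 in PDC), PECAM1 (−0.37 and −0.57) and ERG (−0.42 and −0.81) ran against it, and EGFL7 was at 0.27 and 0.03. Smooth muscle cells or pericytes in some sheets may be a source, since 14 other markers of that list had a median correlation of 0.83 in PDC and 0.89 in NAC, although that test was written after similar correlations had been seen and the pericyte genes KCNJ8 (−0.82 in NAC, −0.6 in PDC) and ABCC9 (−0.91 and −0.55) ran the other way. A contractile state of the chondrocytes themselves was not tested and stays open.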

How the results depend on the processing

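The alternatives were set before the data were examined, apart from edgeR's quasi-likelihood test on recovered reads, TMM scaling and leaving out NAC 5, PDC 14 and PDC 16, which were chosen after seeing the data. Against 2945 changed genes, the alternatives other than the replicate block gave from 2456 without the filter to 3868 with limma-voom and library weights, and no called gene had the opposite sign in any of them. The 2-fold count of 1508 went to 878 with at least 1 CPM in at least 8 libraries, a filter that leaves 13758 genes to test. Leaving out each library gave 2397 to 3471 changed genes, 1315 to 1681 of at least 2-fold, 7 to 12 lists, a difference in spread of 0.001 to 0.053 and a first component difference of 71.28 to 75.363. The added alternatives gave 2801 genes with edgeR, 2953 with TMM and 3240 without NAC 5, PDC 14 and PDC 16. Camera called 10 lists, 4 with a preset correlation of 0.05 and 0 with an estimated correlation. With the replicate block, which leaves 2 residual degrees of freedom, 8 genes changed and the same 8 by at least 2-fold, and 91 of the genes called without it had the opposite sign. Libraries that share a number did not stand out in their deviations from the group means. These correlated by −0.075 for NAC 12 with PDC 12f and −0.006 for NAC 13 with PDC 13. PDC 19f with PDC 19t gave −0.026, ranking 27 among 78 PDC pairs. No pair known to share a donor was available for comparison, so these values cannot tell whether a shared number marks a shared donor. Of values for named genes, called or not, 1670 stayed on their side of the threshold with a library left out, 7 gained a call and 3 lost one. For the other settings without the block, 1013 stayed, 9 gained a call and 5 lost one. Causes were not tested. Depth limits genes near the floor: at 19.19 M reads or more, a group with 0 reads bounds a fold only against 3 reads.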

Other observations

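No explanation is tested in this part, and its genes and relations were chosen after their values were seen. Imprinted neighbours went opposite ways: H19, a noncoding RNA of the same domain as IGF2, rose from 134 ± 251 (48.4 without NAC 5) to 969 ± 1086 (log2 4.24 ± 1.02, limma adjusted p = 0.00656), while IGF2 fell from 27.0 ± 21.1 to 5.36 ± 8.80 (log2 −2.81 ± 0.71, limma adjusted p = 0.00928). The IGF2 call was lost with DESeq2 (adjusted p = 0.101), and several PDC libraries had no IGF2 read. H19 was among the strongest loadings of the second component (−0.085), which ran within both groups. Of the transcription factors in the tendon list, MKX rose from 476 ± 346 to 2534 ± 1034 and SCX from 63.4 ± 24.9 to 634 ± 828, or 421 without PDC 13 (log2 2.59 ± 0.33 and 2.74 ± 0.43, limma adjusted p = 7.98e-06 and 1.10e-04), while EGR1 and EGR2 differed by log2 0.16 and −1.06 and did not pass (limma adjusted p = 0.745 and 0.0869). TNMD, a marker of mature tendon, was at 0.311 ± 0.431 and 1.10 ± 1.96, or 0.602 without PDC 14 (limma adjusted p = 0.527). Cell cycle inhibitors CDKN2A and CDKN2B fell by log2 −0.84 ± 0.26 and −1.25 ± 0.32 (limma adjusted p = 0.0317 and 0.00967), and CDKN1A, another inhibitor, was at 4787 ± 1039 and 4608 ± 1176 (limma adjusted p = 0.808).

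The smooth muscle list mean was set against 5 other list means within each group, 10 relations in all, with exact permutation for NAC and 100000 permutations for PDC. It rose with the fibrous matrix list in NAC (r = 0.80, p = 0.0148, adjusted p = 0.037; rho = 0.93, p = 0.00223, adjusted p = 0.0112) and in PDC (r = 0.78, p = 0.0015, adjusted p = 0.005; rho = 0.64, p = 0.0218, adjusted p = 0.0436), and r was 0.68 and 0.60 without the 2 farthest libraries. It went against the inflammatory list in PDC (r = −0.84, p = 1.5e-04, adjusted p = 0.0015; rho = −0.87, p = 1.7e-04, adjusted p = 0.0017; r = −0.69 without the 2 farthest). The relation with that list in NAC, where r was −0.09 without the 2 farthest libraries, did not pass (r = −0.55, p = 0.158, adjusted p = 0.198; rho = −0.48, p = 0.243, adjusted p = 0.304). It went against the chondrogenic regulators in NAC (r = −0.90, p = 0.00129, adjusted p = 0.005; rho = −0.83, p = 0.0154, adjusted p = 0.0385), where r was −0.49 without the 2 farthest libraries, so the relation rests largely on those. The relation with these regulators in PDC did not pass (r = −0.45, p = 0.116, adjusted p = 0.166; rho = −0.56, p = 0.0491, adjusted p = 0.0818; r = −0.32 without the 2 farthest). For the cartilage matrix list in PDC, rho passed and r did not (r = −0.59, p = 0.0311, adjusted p = 0.0518; rho = −0.70, p = 0.0103, adjusted p = 0.0343; r = −0.46 without the 2 farthest). In NAC that relation turned in sign without the 2 farthest libraries (r = 0.45), and it did not pass (r = −0.33, p = 0.43, adjusted p = 0.43; rho = −0.17, p = 0.703, adjusted p = 0.703). Neither did those with the cell cycle list, in NAC (r = 0.46, p = 0.255, adjusted p = 0.283; rho = 0.31, p = 0.462, adjusted p = 0.513) or in PDC (r = 0.61, p = 0.0268, adjusted p = 0.0518; rho = 0.48, p = 0.0983, adjusted p = 0.14). Without the 2 farthest libraries r for the cell cycle list was 0.38 in NAC and 0.34 in PDC. Whether NAC and PDC differ in these relations was not tested.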
